A study of Mus musculus with 9 samples.

How the data were processed

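Messenger RNA from anastomotic tissue of 9 samples, 3 in each of 3 groups, was captured with poly-T beads and made into libraries of selected fragment size, per the labels' protocols. The submitters' processing notes name CASAVA, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with no role or order for each. They also name a mouse build, and the labels name the mouse. The deposited table does not carry mouse genes: 30561 of its 31252 rows have rat Ensembl identifiers, the other 691 are unannotated loci, and its last gene on chromosome 1 ends at 260398790, beyond the last gene end of 195323493 on that chromosome in mouse GENCODE M21. The files do not decide whether the species label or the annotation is wrong. If mouse reads were aligned to rat sequence, counts of diverged genes would be too low in every library alike. The strand setting of the counting is not given in the sources used here, so overlapping antisense genes cannot be separated.

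The deposited table holds raw read counts per gene, made by the authors, and these counts were used for every test. It also holds FPKM values made by the authors. Each library's deposited FPKM equals the count over gene length times 1 constant, within a relative deviation of 5e-10 for genes above 500 counts, and the constants follow median-of-ratios size factors, not count totals. The FPKM values entered no test. The table has 1 emptied line, which was skipped, and 8560 rows have no count in any library. Totals were 12935702 to 15564842 counts per library, at which 3 counts, the limit set by a count of 0, are 0.193 to 0.232 CPM. Samples of 1 group differed far beyond counting noise (chi-square per degree of freedom of 17.0 to 276 over genes with at least 20 counts), so none was treated as a duplicate.

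Groups were taken from the sample titles. Genes were kept by filterByExpr at a minimum count of 10 and a minimum total of 15, which left 15985, and scaled by TMM. The main test was edgeR 4.0.16's quasi-likelihood F-test in R 4.3.3, with all 9 samples in 1 fit and no covariate, for each pair of groups and for all 3 groups together, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors were derived from the fold change and its p-value. Marker and pathway lists, 31 in number with 431 gene entries, were written before the data were examined, as were the tests of genes and lists, the rule for named genes and the settings other than the 3 named below as added. Further lists of clock, Hox and seminal vesicle genes were chosen after seeing the data, as were the tests of explanations other than that of other splits of the samples. Of the entries in the 31 lists, 401 were matched, 397 by gene name and 4 by the protein's gene name on rows named only by an identifier. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside an estimated correlation. Fry from limma was run too, and is cited only for the neutrophil list with and without the Hox13 covariate. No list called with the preset correlation was called with the estimated one, which ran from 0.0121 to 0.829 over the called lists. A list is termed called, still called or no longer called by the preset correlation, also with a library left out or with a covariate.

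Named genes follow a rule. For each comparison these are up to 8 genes per direction with the largest fold change among those past the threshold, with groups that do not overlap and a mean log2 CPM above 1, leaving out predicted, clone and immunoglobulin or T cell receptor segment names and names that are only an identifier. To these come up to 4 members of smallest adjusted p, past the threshold in the direction of the list, of each list that camera called or that had at least 3 members past the threshold, or, for a called list with none past it, the 2 members of smallest p as values. Where fewer than 4 genes passed in a direction, the 4 of smallest p are given as values. Clone and locus names were counted as identifiers. No gene is named from the test of all 3 groups, and 1 gene that the rule names is not reported here.

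The alternatives were median-of-ratios (RLE) scaling, no filter beyond 1 count, a mean CPM of at least 1, DESeq2 1.42.0, limma voom with sample weights, the replicate number as a block, each library left out in turn, only the groups compared, a fold change limit on top of the threshold, log2 CPM with RLE factors and an estimated correlation for the lists, and simulated groups with no effect for the overlap. A covariate for the Hox13 level, a fit without both Suture+FG libraries lacking Hoxb13 and simulated lists of the same sizes for the overlap were added after seeing the data. The last was added because the test called almost no gene in the simulated groups, so that the lists past the threshold had almost nothing to share. The gene test was tested on simulated data for Suture+Gel against Suture with 200 changed genes. At a 2-fold change it recovered 0 of 200 in 15714 genes, at 4-fold 112 in 15718 genes with 4 false calls, and at 16-fold 169 in 15690 genes with 14 false calls. Settings meant for tables without counts did not apply.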

Results

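Anastomotic tissue collected on day 7 after surgery was profiled by mRNA sequencing in 9 libraries from 3 groups of 3. The groups were sutured tissue (Suture), sutured tissue with a treatment that the labels abbreviate FG and do not expand (Suture+FG), and sutured tissue with the hydrogel under study (Suture+Gel). The stated aim was to learn how the gel acts on postoperative adhesion and anastomotic healing. Replicates 1, 2 and 3 held 13420975, 12935702 and 14883633 counts in Suture, 14854108, 14253164 and 14500391 in Suture+FG and 14335446, 14443180 and 15564842 in Suture+Gel, and 15985 genes were tested. The labels name the mouse, but all 30561 annotated entries of the deposited table carry rat gene identifiers, so the species is left open. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Levels are CPM after TMM scaling, as mean ± SD with n = 3, and fold changes are log2 values with their standard error (SE).

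Single libraries stood apart in tissue markers. In Suture replicate 3, 8 seminal vesicle secretion genes, among them Svs4 and Semg1, took 16.1% of all counts (95% Wilson interval 16.055% to 16.092%), while no other library had more than 35 counts of them. Hoxb13, a homeobox gene of the hindmost body, had 0 counts in Suture+FG replicates 1 and 3, which allows up to 0.202 and 0.207 CPM of the library total, against 161 CPM in Suture+FG replicate 2. It stood at 9.39, 159 and 51.0 CPM in Suture replicates 1, 2 and 3, and at 119.7, 292 and 302 CPM in those of Suture+Gel. Intervals and limits cover counting error only. The first principal component held 55.66% of the variance, with Suture+FG replicates 3 and 1 at one end and Suture+Gel replicates 3 and 2 at the other.

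**Figure D1:**
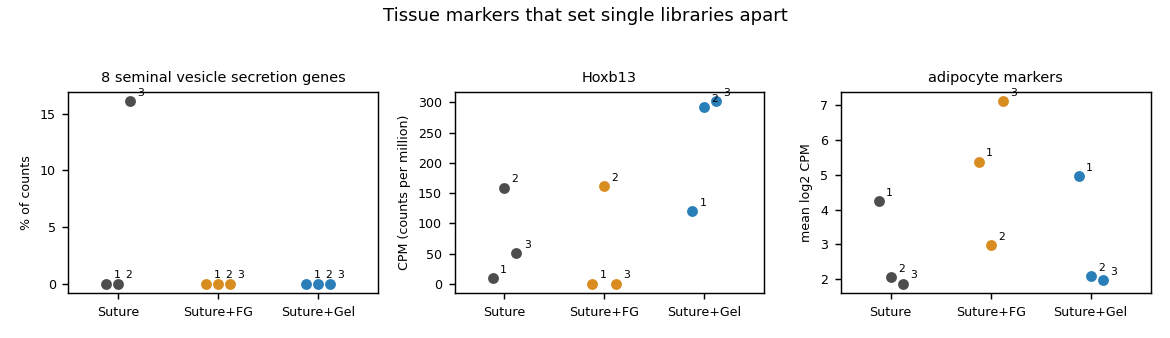
Percent of counts from 8 seminal vesicle secretion genes, Hoxb13 in CPM of the library total, and the mean log2 CPM of adipocyte markers, with 1 point per library, numbered by replicate. Suture replicate 3 stands at 16.1% in the left panel, and Suture+FG replicates 1 and 3 have 0 counts of Hoxb13.

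The first comparison set tissue under the gel against sutured tissue alone. Genes of neutrophils and acute inflammation were far lower in Suture+Gel. Nos2, the inducible nitric oxide synthase, fell from 449 ± 36.1 to 23.6 ± 9.36 CPM (log2 fold change -4.25, SE 0.35, edgeR adjusted p = 0.00665). S100a8, a subunit of calprotectin, fell from 45.4 ± 6.23 to 2.98 ± 1.21 CPM (-3.93, SE 0.33, edgeR adjusted p = 0.00665). Cpa3, a mast cell carboxypeptidase, rose by a log2 fold change of 2.41 (SE 0.39, edgeR adjusted p = 0.0499). Beside these and the other changes of this comparison, the share of counts from mitochondrial genes was 4.53%, 3.06% and 1.15% in Suture replicates 1, 2 and 3 and 5.47%, 6.95% and 4.73% in those of Suture+Gel, without overlap, while it was 3.48%, 5.17% and 3.56% in those of Suture+FG.

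In the list of inflammatory cytokines and chemokines, all 17 tested members had negative fold changes, with a median of -3.41. Of these, 5 passed lower over all genes and 16 when adjusted over the list alone (camera adjusted p = 3.36e-19, and adjusted p = 0.140 with an estimated correlation). Il1b fell by 3.74 (SE 0.43) on the log2 scale, and the monocyte-attracting chemokine Ccl7 fell by 1.97 (SE 0.23). Cxcl2, which attracts neutrophils, had 2193 counts over the Suture libraries and 13 over those of Suture+Gel. Of 11 neutrophil markers, 10 had negative fold changes, 4 passed over all genes and 7 when adjusted over the list alone (camera adjusted p = 5.61e-09, and adjusted p = 0.140 with an estimated correlation). Besides S100a8 these were its partner S100a9 at -3.07 (SE 0.38), the chemokine receptor Cxcr2 at -4.12 (SE 0.46) and the growth factor receptor Csf3r at -3.26 (SE 0.39). The mean log2 CPM of the neutrophil list was 3.58 ± 0.36 in Suture and 1.15 ± 0.57 in Suture+Gel.

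Other genes with large decreases included Il1r2, a decoy receptor for interleukin 1, which fell from 65.2 ± 21.3 to 2.43 ± 0.563 CPM, and Arg1, an arginase, which fell from 95.4 ± 6.07 to 4.31 ± 2.67 CPM. Mmp8, the neutrophil collagenase, had 807 counts in Suture and 28 in Suture+Gel, and Nlrp12 had 391 and 18. Fetub, which encodes fetuin B, had 221 and 11 counts. Prok2 had 602 against 4 counts, and Stfa2l3 had 307 against 3. Stfa2l3 belongs to a family of similar stefin genes among which the counting could split reads. The edgeR adjusted p of these genes lay between 0.00759 and 0.0283.

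Markers of smooth muscle, B cells, mast cells and enteric nerves were higher in Suture+Gel. All 13 smooth muscle markers had positive fold changes with a median of 1.32 (camera adjusted p = 8.81e-08, and adjusted p = 0.420 with an estimated correlation). None passed over all genes and 10 when adjusted over the list alone, with Synpo2 at 1.71 (SE 0.39) and Lmod1 at 1.19 (SE 0.32). B and plasma cell markers had a median of 1.69 over 11 members, with 0 past the test over all genes and 8 when adjusted over the list alone (camera adjusted p = 2.66e-06, and adjusted p = 0.140 with an estimated correlation). The B cell receptor parts Cd79a and Cd79b had log2 fold changes of 2.04 (SE 0.42) and 1.69 (SE 0.40). All 8 mast cell markers had positive fold changes, 1 passed over all genes, Cpa3, and 4 when adjusted over the list alone (camera adjusted p = 2.94e-05, and adjusted p = 0.303 with an estimated correlation), and the median of 1.43 was 2.45 without Suture replicate 3. Among 13 markers of enteric neurons and glia, the neuronal microtubule regulator Stmn2 rose from 0.622 ± 0.355 to 6.30 ± 1.25 CPM (edgeR adjusted p = 0.0472). It was the 1 member past the test over all genes, and 3 passed when adjusted over the list alone (camera adjusted p = 0.000489, and adjusted p = 0.420 with an estimated correlation). The median of that list was 0.54, and it was 0.86 and 0.35 without Suture replicates 1 and 3 and 0.32 and 0.90 without Suture+Gel replicates 1 and 3. Outside the lists, the clock repressor Nr1d1 rose from 6.27 ± 1.93 to 26.5 ± 4.34 CPM, and Ntng1, Enpp5 and Pitpnm2 rose by log2 fold changes of 1.99, 1.17 and 0.94.

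Lists of proliferation, matrix turnover and antioxidant defence had negative medians in Suture+Gel against Suture, and were called with the preset correlation only. All 20 cell cycle genes had negative fold changes with a median of -0.43, 0 passed over all genes and 2 when adjusted over the list alone (camera adjusted p = 6.90e-06, and adjusted p = 0.592 with an estimated correlation), with Birc5 at -1.05 (SE 0.23) and Tpx2 at -0.71 (SE 0.17), and the median was -0.27 without Suture replicate 2. Of 15 matrix proteases and inhibitors, which had a median of -1.76, Mmp8 alone passed over all genes, and 6 lower and 1 higher members passed when adjusted over the list alone (camera adjusted p = 0.000462, and adjusted p = 0.420 with an estimated correlation). Coagulation and fibrinolysis genes had a median of -0.76, with 0 past the test over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.00118, and adjusted p = 0.420 with an estimated correlation). The plasminogen activator Plau and its receptor Plaur had log2 fold changes of -1.46 (SE 0.37) and -1.66 (SE 0.40), and the median of the coagulation list was -0.50 without Suture replicate 1 and -0.51 without Suture+Gel replicate 3. Among 18 antioxidant genes, the mitochondrial superoxide dismutase Sod2 fell from 554 ± 104 to 189 ± 14.5 CPM. It was the 1 member past the test over all genes, and 3 passed when adjusted over the list alone (camera adjusted p = 0.00933, and adjusted p = 0.205 with an estimated correlation). The median of the antioxidant list was -0.27. It was -0.30 for Suture+FG against Suture and -0.12 for Suture+Gel against Suture+FG, where 1 member passed lower over all genes. Camera called the list in neither (camera adjusted p = 0.0823 and 0.531). Monocyte and macrophage markers had a median of -0.70, and Arg1 was the 1 member that passed either way (camera adjusted p = 0.0245, and adjusted p = 0.706 with an estimated correlation). The list was no longer called without Suture replicate 1, where its median was -0.22, or without Suture+Gel replicate 3, where it was -0.35, and the median was -1.11 without Suture+Gel replicate 1 (camera adjusted p from 0.00164 to 0.449 over the 9 libraries left out in turn). Collagens and wound matrix genes had a median of -0.85, and 0 passed either way (camera adjusted p = 0.0245, and adjusted p = 0.714 with an estimated correlation), with Postn at -1.26 (SE 0.50) and Col12a1 at -1.63 (SE 0.65). That list was no longer called without Suture replicate 1, Suture+Gel replicate 2 or Suture+Gel replicate 3, with medians of -0.11, -0.52 and -0.49, and its median was -1.61 without Suture+Gel replicate 1 (camera adjusted p from 2.15e-05 to 0.455 over the 9 libraries left out in turn). Postn was -0.63 without Suture replicate 1, and Col12a1 was -0.98 without that library and -2.70 without Suture+Gel replicate 1. With the Hox13 level as a covariate, a setting chosen after seeing the data, neither the macrophage nor the collagen list was called, with medians of -0.36 and -0.33.

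In edgeR's quasi-likelihood test, 59 genes differed between Suture+Gel and Suture, 8 higher and 51 lower, and S100a8 and the transglutaminase Tgm1, the latter named after its values were seen, were the 2 called with each of the 9 libraries left out in turn. The count was 19, 8 and 18 without Suture replicates 1, 2 and 3, of which replicate 3 held the seminal vesicle transcripts, 39 without Suture+FG replicate 1, and 147, 4 and 2 without Suture+Gel replicates 1, 2 and 3. It was 924 in DESeq2, 784 in limma voom with sample weights and 38 without both Suture+FG libraries lacking Hoxb13.

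**Figure D2:**
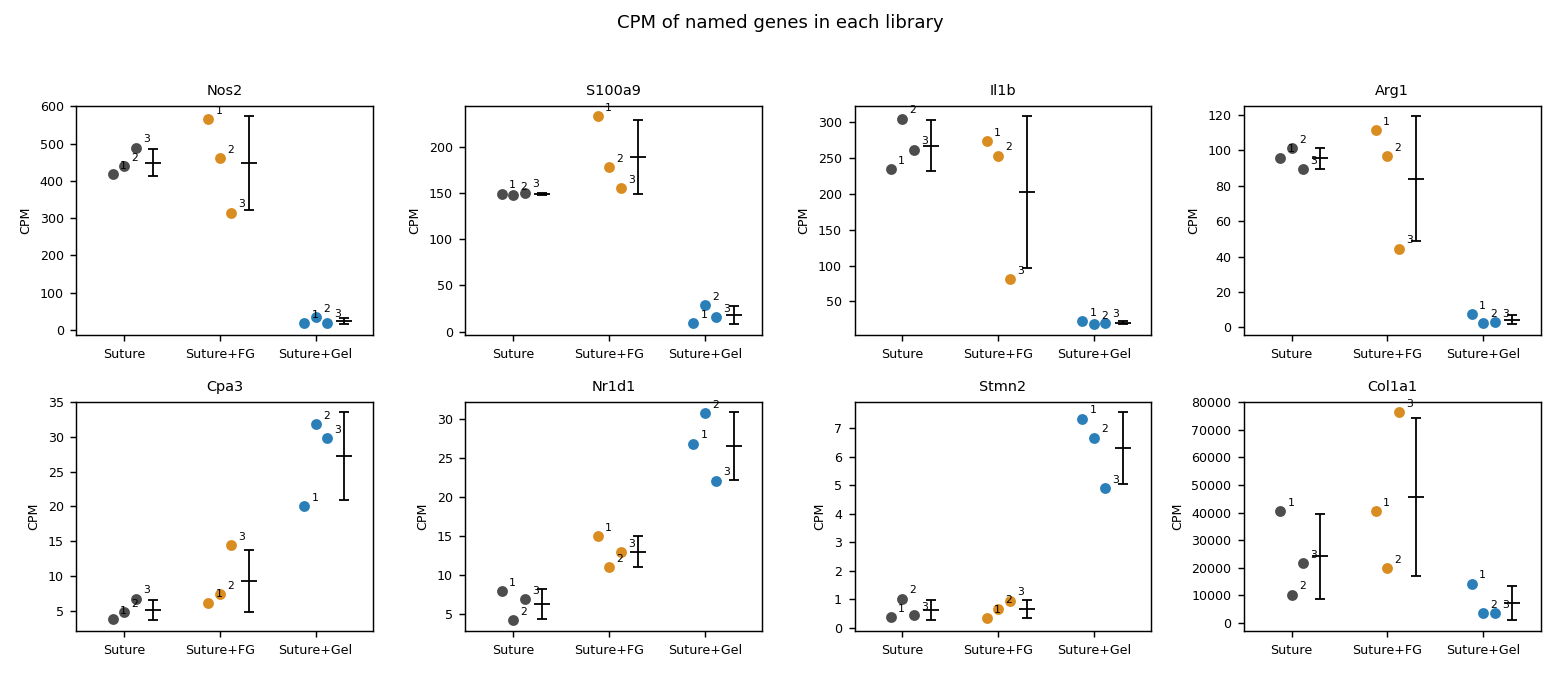
CPM of 8 genes in each library, with points numbered by replicate and bars giving the mean and SD of 3 libraries per group. Nos2, S100a9, Il1b and Arg1 are lower in each Suture+Gel library than in any other, and Col1a1, a fibrillar collagen, ranges from 3532 to 76392 CPM.

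The second comparison set Suture+FG against Suture. No gene passed edgeR's quasi-likelihood test, and the smallest adjusted p was 0.369. At an unadjusted p under 0.05 there were 2140 genes, where 799 would be met on average with no difference. With correlated genes the number by chance can lie far from that average. DESeq2 called 60 and limma voom with sample weights 0. The genes of smallest p are therefore given as values. Nqo1, a quinone reductase, stood at 98.3 ± 17.3 CPM in Suture and 24.7 ± 8.82 CPM in Suture+FG, and Slc51a, part of a bile acid exporter, at 18.3 ± 5.16 and 4.24 ± 1.91 CPM. Hsd3b2 stood at 39.7 ± 27.6 and 9.93 ± 0.904 CPM (log2 fold change -1.998, and -1.25 without Suture replicate 3), and Rpa3 had a log2 fold change of -0.89 (SE 0.18). On the higher side, Ankrd44, Ghdc, Fhl5 and Foxj2 had log2 fold changes of 0.96, 1.61, 1.88 and 0.59.

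Epithelial lists had negative medians in Suture+FG against Suture, and matrix and fat lists had positive ones. The mean log2 CPM of absorptive colon epithelium was 5.68 and 4.68 in Suture+FG replicates 1 and 3, which lacked Hoxb13, against 7.55 in replicate 2, and that of adipocytes was 5.37 and 7.10 against 2.98. All 14 absorptive epithelium markers had negative fold changes with a median of -1.40 (camera adjusted p = 1.14e-05, and adjusted p = 0.617 with an estimated correlation), as had all 11 goblet cell and mucus genes with a median of -1.11 (camera adjusted p = 0.000169, and adjusted p = 0.617 with an estimated correlation) and 14 of 15 tight junction genes with -1.11 (camera adjusted p = 0.000432, and adjusted p = 0.617 with an estimated correlation). Guca2a and Tmigd1 had log2 fold changes of -2.23 (SE 0.64) and -2.26 (SE 0.72), the goblet cell factors Spdef and Agr2 -1.55 (SE 0.43) and -1.31 (SE 0.55), and the junction genes Cldn15 and Tjp1 -1.12 and 0.43. Without Suture+FG replicate 2 the medians of absorptive epithelium, goblet cells and tight junctions were -2.63, -3.16 and -2.40, and without Suture+FG replicate 3 those of goblet cells and tight junctions were -0.66 and -0.59. Agr2 was -2.04 and -0.84 without these libraries, and Tjp1 was 0.26 without Suture replicate 3. All 20 collagens and wound matrix genes had positive fold changes with a median of 0.84 (camera adjusted p = 0.000169, and adjusted p = 0.617 with an estimated correlation), with Bgn at 1.58 (SE 0.71) and Loxl1 at 1.05 (SE 0.47), and without Suture replicate 1 the median was 1.47 and Bgn 2.59. All 10 adipocyte markers had positive fold changes with a median of 2.70 (camera adjusted p = 0.00283, and adjusted p = 0.617 with an estimated correlation), which was 1.28 without Suture+FG replicate 3. Cidec, a lipid droplet protein, stood at 4.59 ± 2.87 CPM in Suture and 37.4 ± 46.7 CPM in Suture+FG, and Cfd, or adipsin, at 64.9 ± 49.9 and 536 ± 650.4 CPM. Their log2 fold changes were 3.02 and 3.05, and 1.21 and 1.35 without Suture+FG replicate 3.

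Endothelium had a median of 0.73 (camera adjusted p = 0.00576, and adjusted p = 0.617 with an estimated correlation), with the receptors Tek and Eng at 0.82 and 1.02, and without Suture replicate 1 the median was 1.10 and Eng 1.58. Monocytes and macrophages had a median of 0.64 (camera adjusted p = 0.0231, and adjusted p = 0.617 with an estimated correlation), with the mannose receptor Mrc1 at 1.06 (SE 0.41) and Retnla at -3.70 (SE 1.17). The list was no longer called without Suture replicate 2, Suture replicate 3 or Suture+FG replicate 1, with medians of 0.58, 0.46 and 0.47, and its median was 1.25 without Suture replicate 1 (camera adjusted p from 0.00281 to 0.131 over the 9 libraries left out in turn), where Mrc1 and Retnla were 1.71 and -2.30. B and plasma cells had a median of 0.71 (camera adjusted p = 0.00283, and adjusted p = 0.617 with an estimated correlation), with Cd79b at 1.64 (SE 0.40) and the B cell factor Pax5 at 6 counts in Suture and 56 in Suture+FG, and that list was no longer called without Suture+FG replicate 2, where its median was 0.71 (camera adjusted p from 0.000682 to 0.0896 over the 9 libraries left out in turn). Cell cycle genes had a median of -0.38 with all 20 negative (camera adjusted p = 0.000330, and adjusted p = 0.617 with an estimated correlation), with Birc5 and Ccna2 at -0.83 and -0.83, and a median of -0.16 without Suture replicate 2. Antimicrobial defence had a median of -0.91 (camera adjusted p = 0.0285, and adjusted p = 0.617 with an estimated correlation), with Retnlb at -3.19 (SE 0.61) and the lectin Itln1 at -4.70 (SE 1.87), which was -0.81 without Suture replicate 3, the library with seminal vesicle transcripts. The list was no longer called without Suture replicate 1, Suture replicate 2 or Suture+FG replicate 3, with medians of -0.92, -0.50 and -0.65, and its median was -2.67 without Suture+FG replicate 2 (camera adjusted p from 0.00167 to 0.130 over the 9 libraries left out in turn). Smooth muscle had a median of -0.53 (camera adjusted p = 0.0321, and adjusted p = 0.617 with an estimated correlation), with Myh11 and Lmod1 at -0.86 and -0.63. It was no longer called without Suture replicate 1, Suture+FG replicate 1 or Suture+FG replicate 3, with medians of -0.22, -0.30 and -0.36, and its median was -0.28 without Suture replicate 3 and -0.97 without Suture+FG replicate 2 (camera adjusted p from 0.00152 to 0.320 over the 9 libraries left out in turn), where Myh11 and Lmod1 were -1.35 and -0.97. No member of these 11 lists passed over all genes, and when adjusted over the list alone 1 B and plasma cell gene and 1 antimicrobial gene did. With the Hox13 level as a covariate, a setting chosen after seeing the data, B and plasma cells, absorptive epithelium and cell cycle were still called, with medians of 0.92, -0.66 and -0.19, and the others were not, with medians of -0.31 for goblet cells, -0.31 for tight junctions, 0.19 for collagens, 0.33 for adipocytes, 0.20 for endothelium, 0.11 for macrophages, -0.49 for antimicrobial defence and -0.28 for smooth muscle. Without both Suture+FG libraries lacking Hoxb13, the medians of adipocytes, smooth muscle and tight junctions were -0.41, 0.0863 and -0.0309.

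The third comparison set the gel against FG. Neutrophil and inflammatory genes were lower in Suture+Gel here too, and neuronal and muscle markers were higher. Epithelial lists had positive medians, but absorptive epithelium and tight junctions in Suture+FG replicate 2 lay among the Suture+Gel libraries. Nos2 stood at 447 ± 126 CPM in Suture+FG (log2 fold change -4.24, SE 0.35, edgeR adjusted p = 0.00547) and S100a8 at 71.6 ± 17.3 CPM (-4.58, SE 0.34, edgeR adjusted p = 0.00350). Hmcn2, a matrix protein of the hemicentin family, rose from 9.91 ± 6.71 CPM in Suture+FG to 206 ± 35.4 CPM (4.37, SE 0.60, edgeR adjusted p = 0.0300). Elavl4, a neuronal RNA-binding protein, had 2 counts over the Suture+FG libraries and 112 over those of Suture+Gel.

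All 17 cytokines and chemokines had negative fold changes, 5 passed over all genes and 16 when adjusted over the list alone (camera adjusted p = 3.09e-12, and adjusted p = 0.479 with an estimated correlation). Il1b and Cxcl1 fell by 3.34 (SE 0.42) and 3.26 (SE 0.44) on the log2 scale, and Cxcl2 had 1646 counts in Suture+FG. All 11 neutrophil markers were negative, with 4 past the test over all genes and 9 when adjusted over the list alone (camera adjusted p = 2.52e-08, and adjusted p = 0.182 with an estimated correlation). Cxcr2, Csf3r and S100a9 had log2 fold changes of -4.45, -3.54 and -3.41. Mmp8, Nlrp12, Prok2 and Stfa2l3 had 1915, 525, 774 and 276 counts in Suture+FG. Il1r2 and Arg1 fell by 4.29 (SE 0.43) and 4.28 (SE 0.49), and Ncf4, a subunit of the phagocyte oxidase, by 1.63 (SE 0.27).

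Among 13 enteric neuron and glia markers, 3 passed higher over all genes, Elavl4 and Stmn2 among them, and 5 when adjusted over the list alone (camera adjusted p = 0.000193, and adjusted p = 0.479 with an estimated correlation), and the median of 1.69 was 2.76 without Suture+FG replicate 2. Stmn2 rose from 0.660 ± 0.305 CPM in Suture+FG to 6.30 ± 1.25 CPM in Suture+Gel. Outside the list, Rims1 of the presynaptic zone rose by 2.87 (SE 0.45) and the neuronal filament gene Prph by 2.85 (SE 0.49), with edgeR adjusted p = 0.0412 and 0.0498. Adcy1, Adamtsl3, Pamr1, Wscd2 and Dtna rose by log2 fold changes of 3.60, 3.22, 2.87, 2.53 and 2.41. Their edgeR adjusted p ran from 0.01755 for Dtna to 0.0496 for Adcy1 and Wscd2. With each library left out in turn, the highest was 0.121 for Dtna and 0.235 for Adcy1. All 13 smooth muscle markers were positive with a median of 1.77, 0 past the test over all genes and 12 when adjusted over the list alone (camera adjusted p = 5.49e-08, and adjusted p = 0.479 with an estimated correlation), with Lmod1 at 1.82 (SE 0.32) and Synpo2 at 2.07 (SE 0.39).

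Epithelial lists had positive medians in Suture+Gel against Suture+FG, whose replicates 1 and 3 lacked Hoxb13. In Suture+FG replicate 2 the mean log2 CPM of absorptive epithelium was 7.55, within the 7.44 to 8.01 of the Suture+Gel libraries. That of tight junctions was 6.18 there, within 6.03 to 6.68, and that of goblet cells 7.70, below 7.79 to 8.76. All 11 goblet cell genes were positive (camera adjusted p = 2.59e-05, and adjusted p = 0.479 with an estimated correlation), with the mucin Muc2 at 2051 ± 939.6 CPM in Suture+FG and 5508 ± 1418 CPM in Suture+Gel, and Spdef at a log2 fold change of 1.59 (SE 0.43). In absorptive epithelium (camera adjusted p = 0.00169, and adjusted p = 0.479 with an estimated correlation) the chloride exchanger Slc26a3 had 2.29 and the microvillus gene Vil1 1.69, and in tight junctions (camera adjusted p = 0.000337, and adjusted p = 0.479 with an estimated correlation) Ocln had 1.81 and F11r 0.84. These were 3.48, 2.82, 3.05 and 1.28 without Suture+FG replicate 2, and the medians of goblet cells, absorptive epithelium and tight junctions, 1.70, 1.55 and 1.39, were 3.48, 2.85 and 2.53 without it. The tight junction median was 0.87 without Suture+FG replicate 3. In stem cell and Wnt genes (camera adjusted p = 0.00968, and adjusted p = 0.479 with an estimated correlation) Lrig1 had 1.33 and Sox9 1.21, and 4 members passed when adjusted over the list alone. That list, with a median of 0.79, was no longer called without Suture+Gel replicate 1, where its median was 0.90 (camera adjusted p from 0.00232 to 0.106 over the 9 libraries left out in turn). In mast cells (camera adjusted p = 0.0117, and adjusted p = 0.479 with an estimated correlation) Cpa3 had 1.55 and the protease Mcpt1 2.38, and 3 passed when adjusted over the list alone, and the median of 1.10 was 0.63 and 1.69 without Suture+FG replicates 1 and 3. Mcpt1 belongs to a family of similar proteases among which the counting could split reads. No member of these 5 lists passed over all genes. With the Hox13 level as a covariate, a setting chosen after seeing the data, mast cells were still called with a median of 1.19, and goblet cells, absorptive epithelium, tight junctions and stem cell genes were not, with medians of 0.39, 0.00, 0.09 and 0.37.

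Matrix, vessel, macrophage and fat lists had negative medians in Suture+Gel against Suture+FG. Collagens and wound matrix genes had a median of -1.69 with 19 of 20 negative, and 6 passed when adjusted over the list alone (camera adjusted p = 2.95e-06, and adjusted p = 0.479 with an estimated correlation), with Postn at -2.02 (SE 0.51) and Col5a1 at -2.13 (SE 0.62). Matrix proteases had a median of -1.99, with Mmp8 past the test over all genes and 8 when adjusted over the list alone (camera adjusted p = 0.000193, and adjusted p = 0.479 with an estimated correlation), and their median was -2.99 without Suture+Gel replicate 1. Of the coagulation genes 7 passed when adjusted over the list alone (camera adjusted p = 0.00124, and adjusted p = 0.479 with an estimated correlation), with Plaur at -1.83 and Plau at -1.58. Monocytes and macrophages had Arg1 past the test over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.000208, and adjusted p = 0.479 with an estimated correlation). Endothelium (camera adjusted p = 0.00124, and adjusted p = 0.479 with an estimated correlation) had the receptors Tie1 at -1.83 and Kdr at -1.46, and its median of -0.95 was -1.68 without Suture+Gel replicate 1. NADPH oxidases had Ncf4 past the test over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.0456, and adjusted p = 0.479 with an estimated correlation). That list, with a median of -1.12, was no longer called without Suture replicates 2 or 3, Suture+FG replicate 1 or Suture+Gel replicates 2 or 3, with medians of -1.11, -1.11, -0.85, -0.96 and -0.91 (camera adjusted p from 0.0220 to 0.0766 over the 9 libraries left out in turn). Adipocytes had a median of -2.11 (camera adjusted p = 0.0271, and adjusted p = 0.596 with an estimated correlation), with Cfd at -2.88 (SE 1.13) and the lipid carrier Fabp4 at -2.30 (SE 0.97), and that median was 0.95 without both Suture+FG libraries lacking Hoxb13. The adipocyte list was no longer called without Suture+FG replicate 3 or Suture+Gel replicates 2 or 3, with medians of -0.88, -1.84 and -1.76, and its median was -3.86 without Suture+Gel replicate 1 (camera adjusted p from 0.00232 to 0.241 over the 9 libraries left out in turn). Cfd was -1.17 without Suture+FG replicate 3, and Fabp4 -3.85 without Suture+Gel replicate 1. With the Hox13 covariate the endothelium, NADPH oxidase and adipocyte lists were not called, with medians of -0.16, 0.0475 and 1.33, and those of collagens, matrix proteases, coagulation genes and macrophages, which were, had medians of -0.40, -1.32, -0.58 and -0.26, against -1.02 and -1.44 without the covariate for coagulation genes and macrophages.

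**Figure D3:**
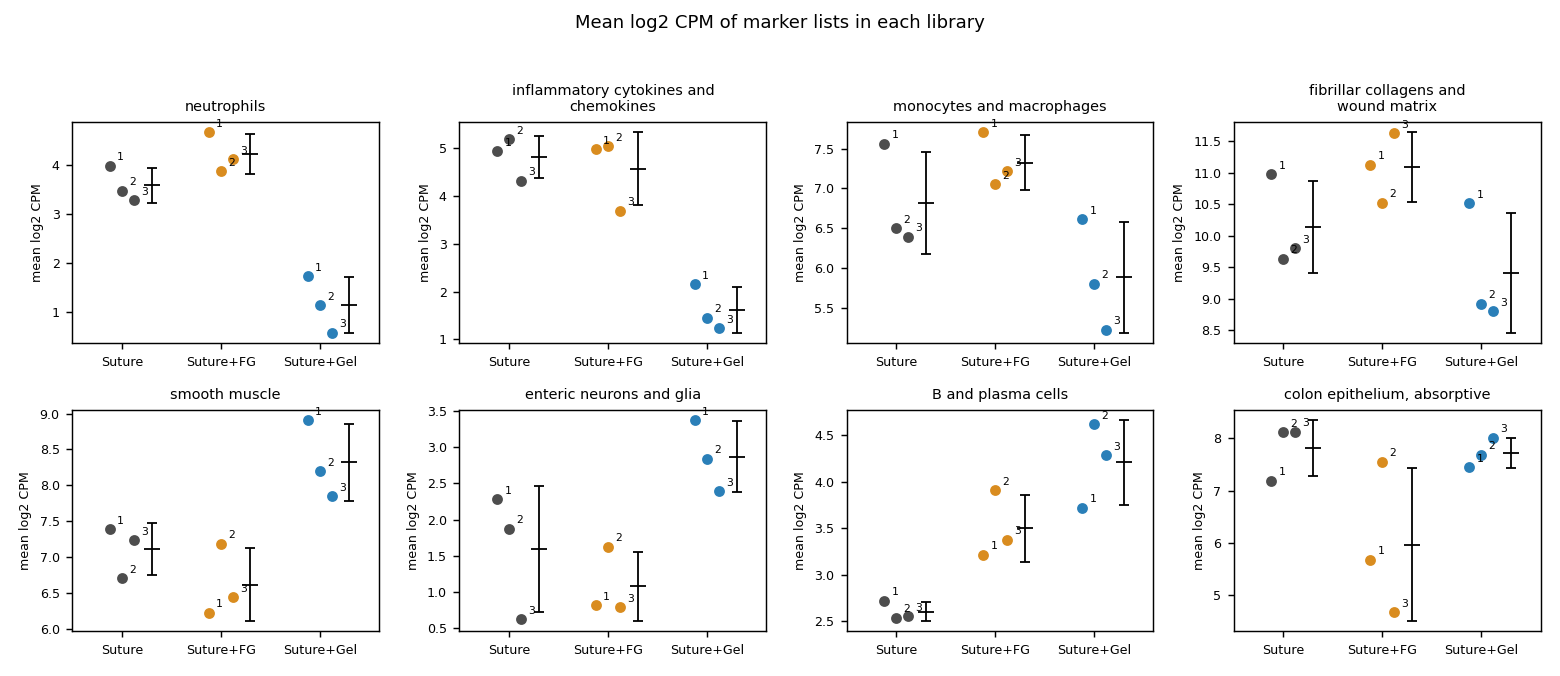
Mean log2 CPM of 8 marker lists in each library, with points numbered by replicate and bars giving the mean and SD of 3 libraries per group. Neutrophil markers stand at 1.15 ± 0.57 in Suture+Gel and 3.58 ± 0.36 in Suture, and absorptive epithelium at 5.68 and 4.68 in Suture+FG replicates 1 and 3.

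In edgeR's test, 101 genes differed between Suture+Gel and Suture+FG, 31 higher and 70 lower, and S100a8 and Tgm1, the latter named after its values were seen, were again the 2 called with each of the 9 libraries left out in turn. Of the lower genes, 45 were among the 51 lower ones of the first comparison, where independent lists would share 0.223. In 50 simulations with no effect, lists of the same sizes made of the genes of smallest p shared 7 to 23 genes with a mean of 14.46, a setting chosen after seeing the data. Each gene was drawn independently there, so with correlated genes the range with no effect may be wider. Of the higher genes, 2 were among the 8 of the first comparison, where independent lists would share 0.0155 and such simulated lists shared 0 to 4, and that overlap therefore lies within the range with no effect. The simulated comparisons also shared the 3 Suture+Gel libraries, so under that model part of the excess of shared lower genes over 0.223 comes from the sharing. The count was 9 without both Suture+FG libraries lacking Hoxb13, 0 with the Suture libraries kept out of the fit, 2272 in DESeq2 and 7864 in limma voom with sample weights. It was 43, 12 and 40 without Suture replicates 1, 2 and 3, 12, 2690 and 38 without those of Suture+FG, and 1170, 4 and 2 without those of Suture+Gel. The 2690 came with only the libraries lacking Hoxb13 left in Suture+FG. The voom weights ran from 0.429 in Suture+Gel replicate 1 to 3.05 in Suture+Gel replicate 2.

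Among the 3 groups together, 41 genes differed in edgeR's test. The count was 10, 3 and 1 without Suture replicates 1, 2 and 3, 14 and 925 without Suture+FG replicates 1 and 2, and 4 and 1 without Suture+Gel replicates 2 and 3.

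Positions are given as the deposited table lists them, which names no build, and these genes are listed there as protein coding. Nos2 (ENSRNOG00000057443) lay on chromosome 10 from 63815308 to 63851210. S100a8 (ENSRNOG00000011557) lay on chromosome 2 from 176167124 to 176167643. Cxcl2 (ENSRNOG00000002792) lay on chromosome 14 from 17181062 to 17183075. Cpa3 (ENSRNOG00000011181) lay on chromosome 2 from 102712589 to 102744203. Stmn2 (ENSRNOG00000011705) lay on chromosome 2 from 93204692 to 93252011. Nqo1 (ENSRNOG00000012772) lay on chromosome 19 from 35295573 to 35310557. Hmcn2 (ENSRNOG00000064166) lay on chromosome 3 from 14588662 to 14738025.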

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

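The Hox13 covariate and the fit without both Suture+FG libraries lacking Hoxb13, which leaves 1 Suture+FG library assumed to vary like the others, were chosen after seeing the data. Unless the construction of a setting is named, the cause was not tested. DESeq2 called 924 changed genes, Suture+Gel against Suture, 60, Suture+FG against Suture, 2272, Suture+Gel against Suture+FG, and 1814 genes differing among the 3 groups. Limma voom with sample weights called 784, 0, 7864 and 5929. RLE scaling and a mean CPM of at least 1 kept each count within 1.5 times. Between Suture+Gel and Suture+FG there were 66 genes with no filter beyond 1 count, which tests more genes, and 0 with only those groups in the fit, which has fewer samples. The Hox13 covariate gave 15 there, 16 among the 3 groups and 7 called lists between Suture+FG and Suture. Without both libraries lacking Hoxb13 there were 38 genes between Suture+Gel and Suture, 9 between Suture+Gel and Suture+FG, 7 among the 3 groups and 6 called lists between Suture+FG and Suture. Camera with an estimated correlation called 0 lists in each comparison. Leaving out each library in turn gave 2 to 147 genes between Suture+Gel and Suture, 0 to 0 between Suture+FG and Suture, 2 to 2690 between Suture+Gel and Suture+FG and 1 to 925 among the 3 groups, with 10 to 15, 10 to 15 and 14 to 18 called lists. For the 48 called results of named genes, 457 values under other settings stayed past the threshold, 263 did not and 0 changed sign.

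With the replicate block, edgeR called 211, 0 and 2167 genes in the comparisons in the order above and 628 genes differing among the 3 groups. The numbers were not shown to pair the samples, since correlations of same-numbered deviations ran from -0.306 to 0.537, and not every sample correlated best with its own number. Between Suture and Suture+Gel they were 0.537, 0.291 and 0.148 for replicates 1, 2 and 3. Suture replicate 2 correlated more with Suture+Gel replicate 3, at 0.412.

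Without both Suture+FG libraries lacking Hoxb13, the medians between Suture+FG and Suture became -0.0309 for tight junctions, 0.0863 for smooth muscle and -0.41 for adipocytes, and Cidec and Cfd became -0.27 and -0.35. Between Suture+Gel and Suture+FG the adipocyte median became 0.95 in that fit and 1.33 with the Hox13 covariate, and Cfd became 0.52 and 0.97. Depth limits genes near 0 in a group, such as Prok2 and Elavl4, for which counts are given in place of folds.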

Other observations

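The clock genes, Ifit3 and Oas1a below were chosen after their values were seen, as were the tests below of leukocytes of every kind, of Suture replicate 3 and of the libraries without Hoxb13, and the Hox13 covariate was chosen after seeing the data. All 10 genes driven through the E-box and D-box arms of the circadian clock had positive fold changes between Suture+Gel and Suture, with a median of 1.23, and 1 passed edgeR's test over all genes, Nr1d1. Between Suture+FG and Suture 9 of them were positive, with a median of 0.46, and 0 passed. Per3 stood at 15.4 ± 5.48 CPM in Suture, 21.1 ± 12.9 in Suture+FG and 50.3 ± 9.15 in Suture+Gel (log2 fold change 1.70 and SE 0.43 for Suture+Gel against Suture, edgeR adjusted p = 0.159), and Dbp at 16.4 ± 8.41, 21.5 ± 9.41 and 44.4 ± 11.9 CPM. Nr1d2 and Per2 had log2 fold changes of 1.23 (SE 0.28) and 1.02 (SE 0.32). Nfil3, which acts against the D-box genes, stood at 50.9 ± 12.1 CPM in Suture and 15.7 ± 6.25 in Suture+Gel (edgeR adjusted p = 0.124). Bmal1 and Npas2, of the opposite phase, had log2 fold changes of -0.24 (SE 0.34) and 1.05 (SE 0.51). Of the 5 genes listed for that phase, Nfil3 among them, 2 had positive and 3 negative fold changes, with a median of -0.22. The time of day of collection is not given in the sources used here.

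T and NK cell markers had a median log2 fold change of -0.02 between Suture+Gel and Suture (camera adjusted p = 0.700). Interferon response genes had a median of 0.23 (camera adjusted p = 0.225). Of these, Ifit3 was lower in Suture+Gel than in Suture (log2 fold change -3.55, edgeR adjusted p = 0.0146) and in Suture+FG (-2.58), while Oas1a was higher in Suture+Gel than in Suture+FG (2.20, edgeR adjusted p = 0.0490). Camera called neither of these lists in any comparison, nor those of TGF-beta signalling, mesothelium, skeletal muscle, red blood cells, exocrine pancreas, squamous epithelium, small intestinal enterocytes, immediate early genes and fatty acid oxidation, and the smallest adjusted p among them was 0.0547, for TGF-beta signalling between Suture+Gel and Suture+FG.

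Neutrophil and inflammatory genes were lower in Suture+Gel than in Suture. A loss of leukocytes of every kind against Suture is argued against by the B and plasma cell list, whose median log2 fold change was 1.69 and stayed between 1.46 and 1.998 with each library left out. Against Suture+FG, where neutrophil genes were lower too, that list had a median of 0.75 with 8 of 11 members positive. Camera did not call it there (camera adjusted p = 0.175), and T and NK cell markers had a median of -0.38 with 8 of 11 negative. Another stretch of gut is argued against as the whole cause, as far as the Hox13 level tracks it. The neutrophil median was -3.07 without and -2.83 with the Hox13 covariate (limma fry adjusted p = 0.00287 and 0.00979), which moved the goblet cell median from 0.56 to -0.24. The covariate varied most within Suture+FG, at -2.059, 5.715 and -2.845 mean log2 CPM in replicates 1, 2 and 3. Its slope therefore leans on that group. The 4 tested Hox paralogs 10 to 12 had median deviations from their medians over the 9 libraries that did not overlap between these groups. They were -0.776, -0.084 and -0.124 in Suture replicates 1, 2 and 3 and 0.424, 1.325 and 1.263 in those of Suture+Gel. Those of paralogs 2 to 6 overlapped. A difference in the stretch of gut between these groups therefore stays open as part of the cause. The covariate does not measure epithelial content, which it could not test. The mean log2 CPM of absorptive epithelium was 7.81 ± 0.54 in Suture and 7.71 ± 0.29 in Suture+Gel. Suture replicate 3 alone is argued against too, since without it 6 of the 9 called members of both lists stayed called and 9 stayed lower. An effect of the gel may account for the pattern, as a hypothesis, and so may any difference in handling or collection time between the groups, which was not tested. Bulk values also do not separate a change in the mix of tissues in a sample from a change within cells. Smooth muscle and enteric nerve markers were higher in the same libraries.

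Suture replicate 3 held more than the seminal vesicle secretion genes. In it 31 genes had at least 100 counts and lay at least 50 times above every other library, and in each of the other libraries 0 genes did. The most abundant were Svs4 with 965741 counts and Semg1 with 714710. RNA of another organ is a candidate source, and how it entered the library stays open. No biological explanation was tested.

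Suture+FG replicates 1 and 3 had 0 counts of Hoxb13. Less epithelium alone is argued against, since the mean log2 CPM of Hoxa13, Hoxb13 and Hoxd13 lay further below its median over the 9 libraries than the absorptive epithelium list did, with differences of -5.70 and -5.49. The 4 tested Hox paralogs 10 to 12 had median deviations of -2.67 and -4.11, and the 13 tested paralogs 2 to 6 had 0.22 and 0.76. Another stretch of gut in those libraries may therefore be the source, a hypothesis found and tested on the same data. Suture replicate 1 lay between, at -3.26 for the mean of the 3 genes.

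Other splits of the samples were counted for each number of changed genes. Of the 10 splits of 6 samples, 1 gave as many genes as the 59 between Suture+Gel and Suture, the highest other giving 0, and 1 as many as the 101 between Suture+Gel and Suture+FG, the highest other giving 1. Between Suture+FG and Suture all 10 gave 0. With 10 splits a share under 0.05 cannot be had. For the 3 groups together, the share of such splits was under 0.05, which argues against chance alone at that level. It does not show that the groups are the main structure of the samples. There 2 of 100 splits gave at least the real 41 genes, 1 of them the real grouping itself. The other of these gave 2923 and put Suture replicate 1 with Suture+FG replicates 1 and 3, Suture replicate 2 with Suture+Gel replicates 2 and 3, and the remaining libraries together. That points to a structure of the samples, and these 3 sets follow the order of the libraries on the first principal component.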
